A study of Mus musculus with 12 samples.

How the data were processed

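RNA sequencing of 12 mouse libraries was used, 6 from female and 6 from male reproductive tracts, each from RNA pooled from 3 animals. Per the labels, total RNA was extracted with the Qiagen RNeasy Mini kit and libraries were made with Illumina TruSeq reagents. Per the submitters' processing notes, TopHat and the mouse genome build mm9 were used. The counting tool, the gene annotation and the method of normalisation are not given in the sources used here. Sequencing run, lane and index were taken per the file headers.

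The deposited values are log2 values for 31618 genes in each female and 31669 genes in each male library, and the authors gave no read counts or library totals. In the deposited values every gene has a median of 0 over the 6 libraries of its sex, so absolute levels and comparisons between the sexes are lost, and only differences between libraries of the same sex were used. The spacing of the low values showed that, before this centring, read counts had been multiplied by 1 factor per library and raised to at least 1. Values at that floor are those of libraries with no reads for the gene or with so few that they came to 1 normalised read or less. The step per library gave the relative depth of the libraries. Depth sets the precision of low values, since a gene with few reads moves in coarse steps, some of them fractions of a read, and no interval from counting error was computed because the total counts are unknown.

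Small shifts between libraries, at most 0.00882 log2 units in the female and 0.00712 in the male set, were removed. The analysis plan, made before the data were examined, had assumed linear expression values or counts with a pseudocount of 1. Because the deposited values were already on a log2 scale, differences of the deposited values were used directly and no pseudocount was added. A gene counted as measured when its highest library reached 20 normalised reads or when its level could not be read because no library was recognised at the floor and its values did not lie on the steps of a low read count, which left 16711 female and 16901 male genes. This minimum was chosen after the unit was seen. A further 12595 female and 12301 male genes had the same value in all libraries and were not used.

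Libraries were grouped by tissue and genotype from the labels. For each tissue, genes were counted for which both libraries with 2 mutant copies of a cluster lay at least 2-fold above, or below, all 3 others, and the count was compared with the 8 pairs of libraries that do not follow a cluster. Each mutant was compared with WT at 2-fold, each compound mutant with the matching single mutant at 2-fold, and the oviduct and the caudal epididymis with the WT uterus and vas deferens at 4-fold. Genes at least 4-fold apart between the oviduct or epididymis and the mutants of the other cluster served to describe the direction of each mutant. The share of separating genes that also lay at least 4-fold apart between the oviduct or epididymis and the other 3 libraries was set beside that of the 8 other pairs, a comparison chosen after the data were seen. The same was done with the WT library alone in place of the other 3. Effects in uterus and vas deferens were correlated across genes. A total of 46 gene lists of pathways and cell types was fixed before the data were examined. The median of a list was placed among the medians of 10000 random lists of the same size. Because levels are lost, random genes were matched on the presence of floor values and on 5 classes of spread among the libraries of the other sex, in place of mean expression. They were drawn independently of each other. A percentile thus does not measure the spread between libraries and can be extreme for genes that vary together. Where a median or the random medians fell on the value shared by genes at the floor, the percentile says nothing and was taken over genes with at most 1 library at the floor, a step chosen after the data were seen. With 1 library per group no statistical test was made.

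Genes were named by a rule fixed before the data were examined. It took the 12 higher and 12 lower genes with the widest gap for each separation, the 5 higher and 5 lower genes for each mutant against WT, the 12 higher and 12 lower genes of each tissue contrast, all Hox genes and up to 4 measured members with the largest absolute difference from each list. The rule asked for at least 3 normalised reads on the higher side, which was applied where the level could be read. Predicted transcripts were counted without being named, and a few results for single genes are not reported here. Symbols shared by more than 1 gene, 241 in each set, were named only where 1 of the genes was measured. Members of gene families with similar sequences, among them the granzymes, keratins, Sprr2 genes and defensins, can share reads, and the counting is not described in the sources used here.

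The counts were repeated with the deposited values unshifted, without the minimum, with a minimum of 5 normalised reads, with the mean of all libraries intact for the cluster in place of WT, with the mean of all 5 libraries of a tissue in place of WT for the tissue contrasts, with an 8-fold definition of tissue genes, with tissue genes defined against WT, and without each library in turn. The recovery of depth, the minimum, the separation of 2 libraries from 3 others and the percentile of a list were tested on simulated data of 30000 genes per set with the relative depths of the real libraries and 200 genes changed by each fold in 2 libraries. In the simulated uterus comparison, 15446 genes were measured, 1 of 14850 unchanged genes was called, and 10.5, 99.5 and 99.5 percent of genes changed 2-, 4- and 8-fold were called. In the simulated vas deferens comparison, 15901 genes were measured, 1 of 15308 unchanged genes was called, and 11, 97 and 99.5 percent of changed genes were called. Genes changed by the threshold itself were thus mostly not called. The simulated spread was a fixed setting without differences of lane, run or dissection, so the rate of false calls does not carry over to the real libraries. Real pairs that follow no cluster gave medians of 26.5 higher and 36 lower genes in the uterus. In the vas deferens these medians were 13.5 and 15.5. A list of 12 genes raised 4-fold lay at percentile 100 in both sets, and 200 lists of 12 unchanged genes had a median percentile of 51.5 among the 15446 and 47.2 among the 15901 measured genes, here with random lists that were not matched. Of these 200 lists, 13 in the female and 16 in the male set lay outside percentiles 2.5 to 97.5, where 10 are expected. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.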

Results

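Gene expression profiles from RNA sequencing were compared across 12 libraries from the reproductive tracts of adult mice, each made from RNA pooled from 3 animals. The 6 female libraries comprised the uterus of 5 genotypes and the WT oviduct, and the 6 male libraries comprised the vas deferens of the same 5 genotypes and the WT caudal epididymis, the tail of the epididymis that continues into the vas deferens. The genotypes were wild type (WT), Hoxa-null (2 mutant copies of the Hoxa9, Hoxa10 and Hoxa11 block), Hoxd-null (2 mutant copies of the Hoxd9, Hoxd10 and Hoxd11 block), compound Hoxa-null (Hoxa-null with 1 mutant Hoxd copy) and compound Hoxd-null (Hoxd-null with 1 mutant Hoxa copy). Hox9 to Hox11 genes encode transcription factors that pattern the posterior body axis and the segments of the reproductive tract, and the series was collected to characterise the molecular changes that follow their mutation. There was 1 library per tissue and genotype, so no difference has a replicate check, no error or p-value is given, and a difference of at least 2-fold describes the libraries compared. Groups were set by tissue and genotype, and no stage of the oestrous cycle was used. Any difference in stage between the female pools cannot be told apart from genotype. Total read numbers are not given in the deposited values. The relative depth recovered from them spanned 1.34-fold from the shallowest to the deepest female library and 1.51-fold among the male libraries. Unless another reference is named, the value given for a gene is its log2 difference from the WT library of the same tissue, mutant minus WT. The libraries were sequenced in lanes 1 and 2 of a shared run and in a separate run. Lane 1 held the WT and Hoxa-null uterus and the WT vas deferens, lane 2 the other 3 uteri and the Hoxa-null, Hoxd-null and compound Hoxa-null vas deferens, and the separate run the oviduct, the epididymis and the compound Hoxd-null vas deferens, each in a different lane. Whether these lanes held other libraries is not known. A library with no reads for a gene, or too few to exceed 1 normalised read, stands at 1 normalised read, so differences against such a library understate the contrast.

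The targeted genes were examined first. Hoxa11 (Gene ID 15396, chromosome 6, start 52192105, mm9) was lower in both Hoxa-null uteri, at -2.74 in the Hoxa-null and -3.11 in the compound Hoxa-null library, and in both Hoxa-null vasa deferentia, at -2.29 and -3.20. Its value was -1.03 in the compound Hoxd-null uterus, which carries 1 mutant Hoxa copy, and -0.83 in the matching vas deferens. Hoxa10 (Gene ID 15395, chromosome 6, start 52181196) stood at -1.06 and -0.41 in the Hoxa-null and compound Hoxa-null uterus and at -0.80 and -0.88 in the vas deferens. Hoxa9 (Gene ID 15405, chromosome 6, start 52174053) stayed within 2-fold of WT in these 4 libraries, at -0.34 and 0.27 in the uterus and 0.61 and 0.33 in the vas deferens, and was at 1.65 in the compound Hoxd-null vas deferens. Hoxd11 (Gene ID 15431, chromosome 2, start 74520450) was at -2.47 and -1.17 in the Hoxd-null and compound Hoxd-null vas deferens and at -0.60 and -1.58 in the uterus. In the Hoxa-null and compound Hoxa-null libraries it stood below WT too, at -0.74 and -1.35 in the uterus and -0.88 and -1.45 in the vas deferens. Hoxd9 (Gene ID 15438, chromosome 2, start 74535820) was more than 2-fold lower in the Hoxd-null vasa deferentia, at -1.29 and -1.20, but not in the Hoxd-null uteri, at -0.0043 and -0.25. Hoxd10 (Gene ID 15430, chromosome 2, start 74530028) was within 2-fold of WT in the same 4 libraries, at 0.57 and 0.26 in the uterus and -0.27 and 0.49 in the vas deferens. The labels do not state the kind of allele, so a mutant transcript can still be made and counted, and these values neither check nor contradict the genotype labels.

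Hox genes outside the mutated blocks also differed. In the uterus Hoxc9 (Gene ID 15427, chromosome 15, start 102807463) was at 4.16 and 4.98 and Hoxc10 at 4.28 and 4.69 in the Hoxa-null and compound Hoxa-null libraries. All 7 measured Hoxc genes were at least 2-fold higher than WT in both, with medians of 2.93 and 3.30. Of the 6 genes Hoxa2 to Hoxa7, on the anterior side of the mutated block, 5 were at least 2-fold higher than WT in the Hoxa-null and 6 in the compound Hoxa-null uterus, with Hoxa4 at 1.99 and 2.31, Hoxa6 at 2.46 and 3.07 and Hoxa2 at 0.73 and 1.53. In the compound Hoxd-null uterus all 6 were also higher than WT, with Hoxa6 at 1.68 and Hoxa7 at 1.57, and 0 in the Hoxd-null uterus, but against the mean of the 3 Hoxd-intact uteri Hoxa4, Hoxa5 and Hoxa6 of the compound Hoxd-null uterus turned to -0.43, -0.061 and -0.16. In the Hoxd-null uteri 4 and 6 of the 7 Hoxc genes were at least 2-fold higher than WT, with Hoxc9 at 1.68 and 3.37 and Hoxc10 at 2.23 and 3.99. Against the mean of the 3 Hoxd-intact uteri the Hoxc median of the Hoxd-null uterus turned to -1.14. Of these 3 uteri 2 are Hoxa-null, with Hoxc genes above WT themselves, so this direction holds against WT only. In the vas deferens the most posterior Hox genes were lower where Hoxa9 to Hoxa11 were mutated: Hoxa13 (Gene ID 15398, chromosome 6, start 52208852) was at -3.56 and -3.61 and Hoxd13 (Gene ID 15433, chromosome 2, start 74506367) at -1.68 and -1.59, against -0.35 and 0.31 for Hoxa13 and 0.15 and 0.29 for Hoxd13 in the Hoxd-null libraries. Hoxa4 was at 1.80 and 3.84 and Hoxc9 at 1.73 and 1.89 in the same Hoxa-null vasa deferentia, and the compound Hoxd-null vas deferens had 2.29 and 2.35 for these genes. Of 8 measured Hoxb genes in the uterus, 3 were at least 2-fold lower in the Hoxd-null library, Hoxb4, Hoxb5 and Hoxb6 at -1.11, -1.38 and -1.04, and 0 differed by 2-fold in the other 3 mutants.

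**Figure D1:**
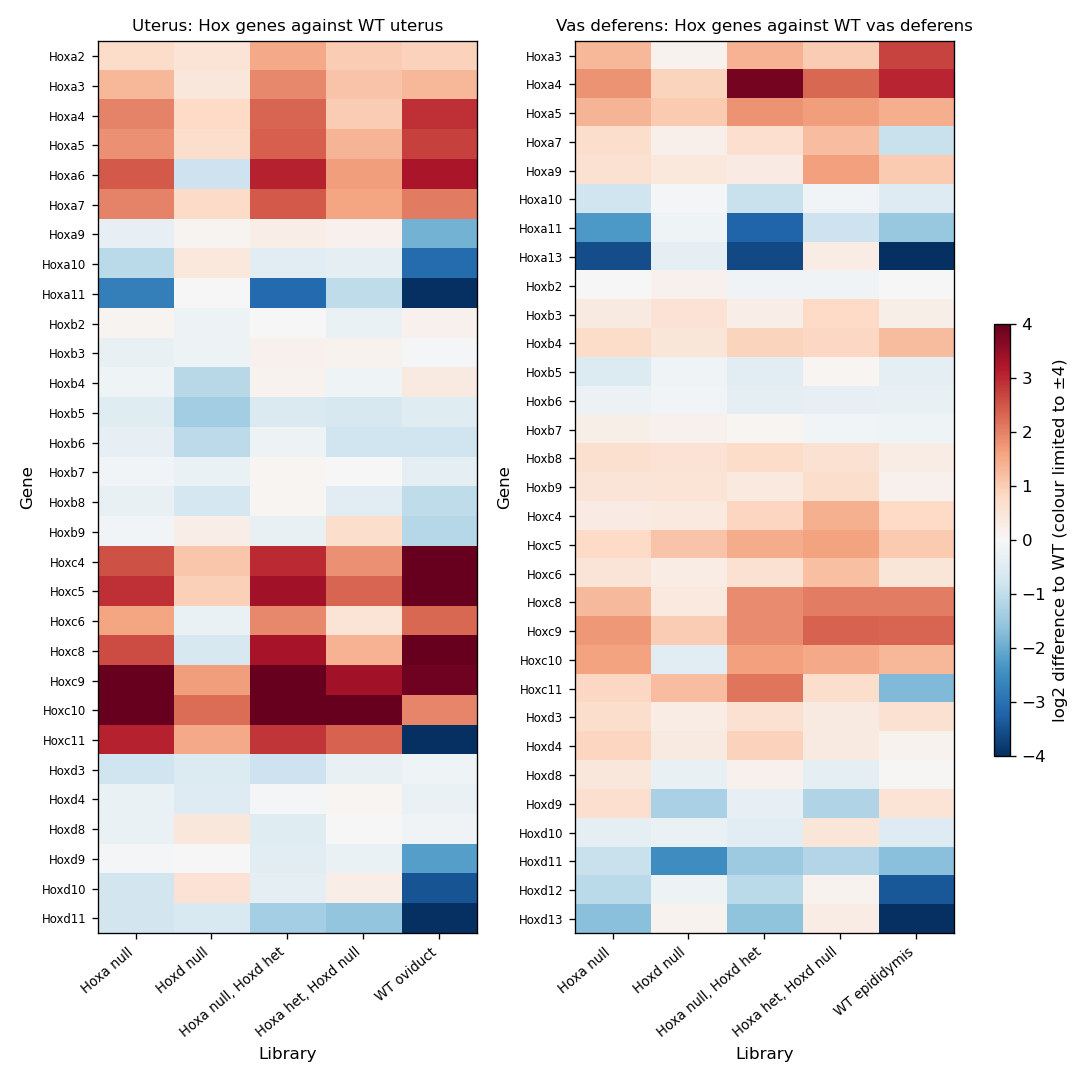
Log2 difference from the WT library of the same tissue for measured Hox genes (vertical axis, ordered by cluster) in the 4 mutant uterus and 4 mutant vas deferens libraries and in the WT oviduct and WT caudal epididymis (horizontal axis), with 1 pooled library per column. Hoxa11 lies between -3.20 and -2.29 in the 4 libraries with 2 mutant Hoxa copies, while Hoxc9 reaches 4.98 in the uterus.

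The genes that separated the 2 Hoxa-null uteri from the 3 others included genes of stratified epithelium on the higher side and of cytotoxic lymphocytes on the lower side. Both Hoxa-null uteri lay at least 2-fold above all 3 Hoxa-intact uteri for 164 genes and at least 2-fold below them for 180. Dsc3, a desmosomal cadherin of stratified epithelia, was at 8.14 and 5.42 in the Hoxa-null and compound Hoxa-null library, Krt13, a keratin of stratified mucosal epithelium, at 6.24 and 4.17, and Krt15, a basal-layer keratin, at 5.64 and 5.43. Aldh3a1, an aldehyde dehydrogenase of squamous and corneal epithelium, had the widest separation, 4.54 log2 units between the nearest libraries, and was at 7.00 and 6.67. Gsta1, a glutathione S-transferase, Sox15, a Sox transcription factor, and Fgfbp1, which releases fibroblast growth factors from the matrix, were at 3.57 and 3.73, 4.40 and 3.96, and 4.08 and 2.95. Tprg, Bpil2, Lypd2, Wfdc6a and the organic anion transporter Slco1a5 completed the 12 most separated higher genes, with gaps from 2.56 to 3.31. On the lower side stood Gzmc, Gzmd and Gzmg, granzymes of cytotoxic lymphocytes, at -5.54 and -5.93, -6.59 and -6.59, and -6.76 and -6.76. Crmp1, a cytosolic phosphoprotein of growing axons, was at -4.73 and -5.13, Dmbt1, a secreted scavenger-receptor protein of mucosal epithelia, at -5.86 and -7.70, and Cyp21a1, the steroid 21-hydroxylase, at -3.33 and -5.65. Trim60, Tspan10, Aspg, the milk-fat protein gene Btn1a1, Zmat4 and the secreted phospholipase Pla2g2e had gaps between 3.15 and 3.52.

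Of 14 measured genes of basal and stratified squamous epithelium, 13 were at least 2-fold higher and 0 lower in the Hoxa-null uterus, with a median of 5.08 above all of 10000 random lists (percentile 100), and 10 were higher and 1 lower in the compound Hoxa-null uterus, with a median of 3.04 (percentile 100). Krt5 and Krt14, the keratin pair of basal cells, were at 7.31 and 5.55, and 6.98 and 4.22, and Col17a1, a hemidesmosomal collagen, at 5.99 and 5.17. In the same libraries Hoxa13, a Hox gene of the most posterior tract, stood at 17.1 and 8.01 normalised reads, against 2.19 in WT, 1 in the Hoxd-null and 2.74 in the compound Hoxd-null uterus. All of these lie below the minimum of 20 normalised reads, so Hoxa13 did not count as measured in the uterus. The squamous median of the compound Hoxd-null uterus was at least 2-fold above WT as well. Against the mean of the Hoxd-intact uteri, which include both Hoxa-null libraries, it turned to -1.22. All natural killer cell genes that differed were lower: 8 of 9 in the Hoxa-null and 9 of 9 in the compound Hoxa-null uterus, with medians of -1.89 and -2.04 at percentiles of 0.04 and 0.01. Gzma, Gzmb and Klre1 stood at -2.66 and -2.04, -2.63 and -3.08, and -2.72 and -3.63. Interferon-induced genes had 8 of 20 members lower in the Hoxa-null and 2 lower in the compound Hoxa-null uterus, and progesterone-induced genes had 9 and 6 of 14 lower, among them Areg, an epidermal growth factor receptor ligand, at -3.95 and -2.20 and the retinoic acid hydroxylase Cyp26a1 at -3.15 and -3.64. Of 17 uterine stroma genes, 3 were higher and 2 lower in the Hoxa-null and 3 higher and 4 lower in the compound Hoxa-null uterus. Eya1, a transcriptional coactivator, was at -3.85 and -3.76, and Nog, a BMP antagonist, was at -3.90 and -6.19. Markers of mesothelium were higher by medians of 1.0 and 1.42, and markers of adipocytes had medians of -1.11 and -0.16. Other ways of choosing 2 of the 5 uteri gave at most 109 higher genes and 101 lower, both for WT with Hoxd-null, and medians of 26.5 and 36 over 8 pairs. Within lane 1 the Hoxa-null and WT uterus differed by 997 higher and 1201 lower genes, and within lane 2 the compound Hoxa-null uterus lay above both Hoxd-null libraries for 870 and below them for 731. With fewer libraries to separate the counts were larger, at 258 higher and 385 lower without the WT, 568 and 425 without the Hoxa-null, 375 and 456 without the compound Hoxa-null and 302 and 310 without the compound Hoxd-null library. The comparison without WT sets the Hoxa-null against the Hoxd-null pair and cannot separate the clusters.

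The genes that separated the 2 Hoxd-null uteri from the 3 others included genes of myeloid cells. Both Hoxd-null uteri lay at least 2-fold above all 3 Hoxd-intact uteri for 151 genes and below them for 57. S100a8 and S100a9, the subunits of neutrophil calprotectin, were at 4.48 and 3.69, and 4.86 and 4.39 in the Hoxd-null and compound Hoxd-null libraries, Csf3r, the receptor for granulocyte colony-stimulating factor, at 2.92 and 2.66, and Cebpe, a transcription factor of granulocyte maturation, at 4.85 and 4.94. Nlrp12, Slfn1 and Slfn4, which are expressed in leukocytes, were at 4.96 and 4.90, 4.09 and 4.31, and 2.58 and 4.06. The epithelial barrier gene Sprr2b was at 2.49 and 3.85, Tubb3, a neuronal beta-tubulin, at 2.52 and 2.62, and Ldhc, the lactate dehydrogenase of male germ cells, at 3.07 and 2.46. H28 had the widest separation, 5.32 log2 units, and Ceacam12 was at 3.43 and 5.89. The lower genes included Guca2b, which encodes uroguanylin, at -5.69 and -4.56, the water channel Aqp8 at -6.19 and -6.50, Tac2, which encodes neurokinin B, at -5.09 and -5.50, the cation exporter Slc47a1 at -3.13 and -4.39 and the paraoxonase Pon1 at -1.46 and -1.72. Pnliprp2, Cpamd8, Sdr16c6, Cntn4, Sorcs3, Ggt6 and Zcwpw2 had gaps from 1.46 to 2.46.

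Immune lists were higher as groups than in WT in both Hoxd-null uteri, where the genotype cannot be told apart from other differences between the pooled animals. Macrophage genes had 12 of 12 members at least 2-fold higher in the Hoxd-null and 11 in the compound Hoxd-null uterus, with medians of 1.19 and 1.36 and percentiles of 100 and 100. The scavenger receptor genes Cd163 and Mrc1 were at 1.66 and 2.52, and 1.75 and 1.89. Neutrophil genes had 6 of 9 higher in each, with Retnlg at 7.06 and 6.45, and medians of 2.21 and 2.57. B and plasma cell genes had 8 and 7 of 8 higher, with the B cell coactivator gene Pou2af1 at 2.19 and 1.81. Chemokine genes had 13 and 17 of 25 higher, with Cxcl13, which attracts B cells, at 3.40 and 5.21 and Cxcl2, which attracts neutrophils, at 2.71 and 4.28. Eosinophil and mast cell genes had 8 and 8 of 11 higher, with the eotaxin receptor Ccr3 at 5.22 and 5.73 and Siglec5 at 4.24 and 3.70. Several of these genes were also above WT in the Hoxa-null and compound Hoxa-null uterus, with Cd163 at 1.88 and 2.06, Mrc1 at 1.89 and 2.04, Retnlg at 1.86 and 5.17, Cxcl13 at 3.24 and 4.37 and Ccr3 at 2.20 and 4.26. For these genes WT was the lowest of the 5 uteri. Cxcl2 and Pou2af1 were at 3.22 and 1.68 in the compound Hoxa-null uterus. In the Hoxa-null and compound Hoxa-null uterus the list medians were 0.07 and 0.27 for macrophage, 0.03 and -0.03 for neutrophil, 0.33 and 1.27 for B and plasma cell, 0.07 and 0.54 for chemokine and 1.37 and 1.32 for eosinophil and mast cell genes. Oestrogen-induced genes had 8 of 14 members higher in the compound Hoxd-null and 2 in the Hoxd-null uterus. Adipocyte genes had 8 of 11 lower in the compound Hoxd-null uterus, with a median of -3.16, against 3 in the Hoxd-null uterus. The widest alternative pair, WT with Hoxd-null, gave 109 higher genes and 101 lower, more lower genes than this separation. Leaving out the WT uterus gave 385 higher and 258 lower, the mirror image of the Hoxa comparison without WT, the Hoxd-null uterus 425 and 294, the compound Hoxa-null uterus 342 and 118, the compound Hoxd-null uterus 278 and 297, and the Hoxa-null uterus 155 lower genes. Within lane 2 the comparison is likewise the mirror image of the Hoxa comparison, with 731 higher and 870 lower, and neither of these 2 can separate the clusters.

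Against WT alone, each mutant uterus was lower for a set of gland transcripts. Prss28, an implantation serine protease gene expressed in uterine glands, was at -8.01, -12.57, -12.83 and -12.83 in the Hoxa-null, Hoxd-null, compound Hoxa-null and compound Hoxd-null uterus, its neighbour Prss29 at -7.20, -11.32, -11.36 and -11.30, and the trypsin inhibitor gene Spink3 at -7.09, -7.32, -6.84 and -12.09. Across 13 measured gland genes, 8, 6, 8 and 7 were at least 2-fold lower, with medians of -1.08, -0.97, -2.06 and -1.36. These values rest on the WT library, since Prss28 and Prss29 in the Hoxa-null uterus were at 0.46 and 0.34 against the mean of the 3 Hoxa-intact uteri.

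The Hoxa-null uterus differed from WT by at least 2-fold for 997 higher and 1201 lower genes of 16711 measured. Its 5 highest named genes were Tmprss11bnl at 9.22, Krt6b at 8.38, Dsc3, Krt6a at 7.99 and Pitx1, a homeodomain factor of hindlimb and pituitary, at 7.71. Its lowest included Col22a1, a collagen of tissue junctions, at -6.80, with -1.59, -4.80 and -6.80 in the Hoxd-null, compound Hoxa-null and compound Hoxd-null uterus. In the compound Hoxa-null uterus 1433 genes were higher and 1131 lower, with Pitx1 at 6.32, Tmprss11bnl at 6.10, Lilrb3 and Ybx1-ps2, at 7.23 here and 7.50 in the compound Hoxd-null uterus, among the highest, and the granzyme gene Gzmf at -6.85 and Lcn13 at -7.50 among the lowest. The Hoxd-null uterus had 1033 higher and 960 lower genes, with Mettl7a2, Lilrb3 and Kap, an androgen-regulated kidney protein gene, on the higher side and the secretoglobin gene Scgb3a1 on the lower. In the compound Hoxd-null uterus 1329 genes were higher and 1047 lower. There Kap was the highest named gene, Hsd3b1, a steroid dehydrogenase of ovary and adrenal gland, was at 8.08, and Cyp11a1, the side-chain cleavage enzyme of steroid synthesis, at 6.34. Hsd3b1 and Cyp11a1 are among the ovarian genes that were also high in the oviduct library described below. The origin of their transcripts in the compound Hoxd-null uterus was not tested. Tm4sf4 and the thyroid hormone carrier gene Ttr were among the lowest. All 4 comparisons share the WT library. In the Hoxa-null, Hoxd-null, compound Hoxa-null and compound Hoxd-null uterus Lilrb3 was at 6.23, 6.95, 6.53 and 7.52, Mettl7a2 at 5.82, 7.52, 5.21 and 7.54 and Kap at 3.37, 5.91, 3.82 and 9.14. In the same order Scgb3a1 was at -4.76, -5.93, -6.60 and -4.73, Tm4sf4 at -4.78, -5.70, -4.37 and -8.28 and Ttr at -3.16, -1.03, -4.27 and -7.16. WT was the lowest or highest of the 5 uteri for these genes. Against the mean of the intact uteri Kap turned to -1.65 in the Hoxa-null and -1.19 in the compound Hoxa-null uterus, Ttr to 1.45 and Col22a1 to 2.28 in the Hoxd-null uterus and Tm4sf4 to 0.29 in the compound Hoxa-null uterus. The compound Hoxa-null library differed from the Hoxa-null library by 1111 higher and 816 lower genes, and the compound Hoxd-null from the Hoxd-null library by 886 and 716. These pairs carry the smallest genotype differences in the uterus, and the first pair also lies across lanes 1 and 2.

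The oviduct was compared with the uterus to define the next more anterior female segment. Genes of motile cilia were higher in the oviduct: 29 of 30 measured multiciliated cell genes were at least 2-fold higher and 0 lower than in the WT uterus, with a median of 7.22 at percentile 100. Among the highest genes were Sec14l3 at 12.47, Spata18 at 12.42, Cdhr3 at 11.64, Sntn, which encodes the ciliary-tip protein sentan, at 10.95, and Ccdc108, Ccdc153, Ccdc135, Wdr52, Zfp474 and Kndc1 between 11.07 and 12.17. Ovgp1, the oviduct-specific glycoprotein, was at 5.14. Ovarian genes were higher too, 10 of 11 by at least 2-fold, with Cyp11a1 at 10.82, the luteinising hormone receptor gene Lhcgr at 6.99 and Hsd3b1 at 12.27. The Y-linked genes Kdm5d and Uty were at 4.90 and 3.67 in the oviduct against the WT uterus, and the X-inactivation transcript Xist, named after its values were seen, at -1.03. Lower in the oviduct were Clca3, a goblet-cell secreted protein gene, at -11.40, the aldose reductase-like gene Akr1b7 at -11.03, the protease inhibitor gene Spink12 at -10.56, Cyp21a1 at -9.08, Prss28 at -10.41, Ttr at -7.16, and Serpina1f, Entpd8, Semg1, Spink3, Dlx6as and Sprr2a3 between -9.91 and -7.43. Semg1, a seminal vesicle gene, was also 3.42 log2 units higher in the lane 2 than in the lane 1 uteri. Cell-cycle genes had 22 of 24 members lower, with Plk1, a mitotic kinase, at -3.14. Prss28 and Spink3 were also far below WT in each mutant uterus, so for these genes the contrast rests on the WT uterus. In all, 1469 genes were at least 4-fold higher and 588 lower. The oviduct library came from another sequencing run than every uterus library, so tissue and run cannot be told apart. Because it also held ovarian and Y-linked transcripts, genes high in this library need not come from the oviduct itself. The same limit holds for the oviduct-high genes used below.

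The direction of the mutant uterus relative to the oviduct was examined with genes at least 4-fold apart between the oviduct and uteri that do not enter the difference. Over 924 oviduct-low genes the median difference from WT was -0.18 in the Hoxa-null and -0.19 in the compound Hoxa-null uterus (both percentile 0), and over 418 such genes it was 0.38 in the Hoxd-null and 0.41 in the compound Hoxd-null uterus (both percentile 100). The percentiles here compare with genes drawn independently and do not measure the spread between libraries. Over 1646 oviduct-high genes the median of the Hoxa-null uterus was the value shared by 130 of them at the floor in both libraries, and that of the compound Hoxa-null uterus was 0.09. Over 1355 such genes the Hoxd-null and compound Hoxd-null uterus had medians of -0.13 and -0.09. With at most 1 library at the floor, the oviduct-high medians were -0.056 (percentile 15.8) in the Hoxa-null and 0.26 (percentile 100) in the compound Hoxa-null uterus over 1307 genes, and -0.27 and -0.20 (both percentile 0) in the Hoxd-null and compound Hoxd-null uterus over 1031. Of the 164 genes that separated the Hoxa-null uteri on the higher side, 90 (54.9%) were at least 4-fold higher in the oviduct than the mean of the 3 Hoxa-intact uteri, and of the 180 lower genes 87 (48.3%) were lower. The same 3 libraries set both comparisons, which builds in overlap. The other 8 pairs of uteri, treated in the same way, gave 30.8 to 71.4% of their higher and 2.86 to 50.7% of their lower genes. Among them were 55.2% of 58 higher genes for WT with compound Hoxa-null and 50.7% of 73 lower genes for WT with Hoxa-null. In this comparison the Hoxa-null shares thus lie within the range of other pairs. With the oviduct set against the WT uterus alone, the Hoxa-null shares were 59.1 and 47.2%, above those of the 8 other pairs. These pairs then gave at most 57.1% (of 7 genes) on the higher side. On the lower side their largest share was 18 of 45 genes, for compound Hoxa-null with compound Hoxd-null. Pairs that hold WT are lowered by construction. Against the WT uterus, the oviduct was at 4.75 for Aldh3a1, 4.61 for Fgfbp1, 4.38 for Slco1a5, -5.93 for Gzmc and -4.93 for Crmp1. Of 30 multiciliated cell genes, 7 were at least 2-fold higher and 8 lower in the Hoxa-null and 3 higher and 7 lower in the compound Hoxa-null uterus. With an 8-fold definition of the lists, the oviduct-low medians were -0.61, -0.76 and 1.04 in the Hoxa-null, compound Hoxa-null and compound Hoxd-null uterus. With lists made against the WT uterus, which the difference shares, they were -0.996 and -1.28 in the Hoxa-null and compound Hoxa-null uterus and turned to -0.14 and -0.17 in the Hoxd-null and compound Hoxd-null uterus, and the oviduct-high median of the compound Hoxa-null uterus was 0.35. Without the minimum on coverage, which adds genes at the floor, the oviduct-high medians of the compound Hoxa-null, Hoxd-null and compound Hoxd-null uterus were near 0, at 0.0011, -0.018 and -0.00074. Leaving the compound Hoxa-null uterus out of the definition of the lists brought the oviduct-low medians of the Hoxd-null and compound Hoxd-null uterus to 0.22 and 0.27, and in the compound Hoxa-null uterus the oviduct-high median went from 0.09 to 0.0011 without the Hoxd-null uterus and to 0.14 without the compound Hoxd-null uterus.

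**Figure D2:**
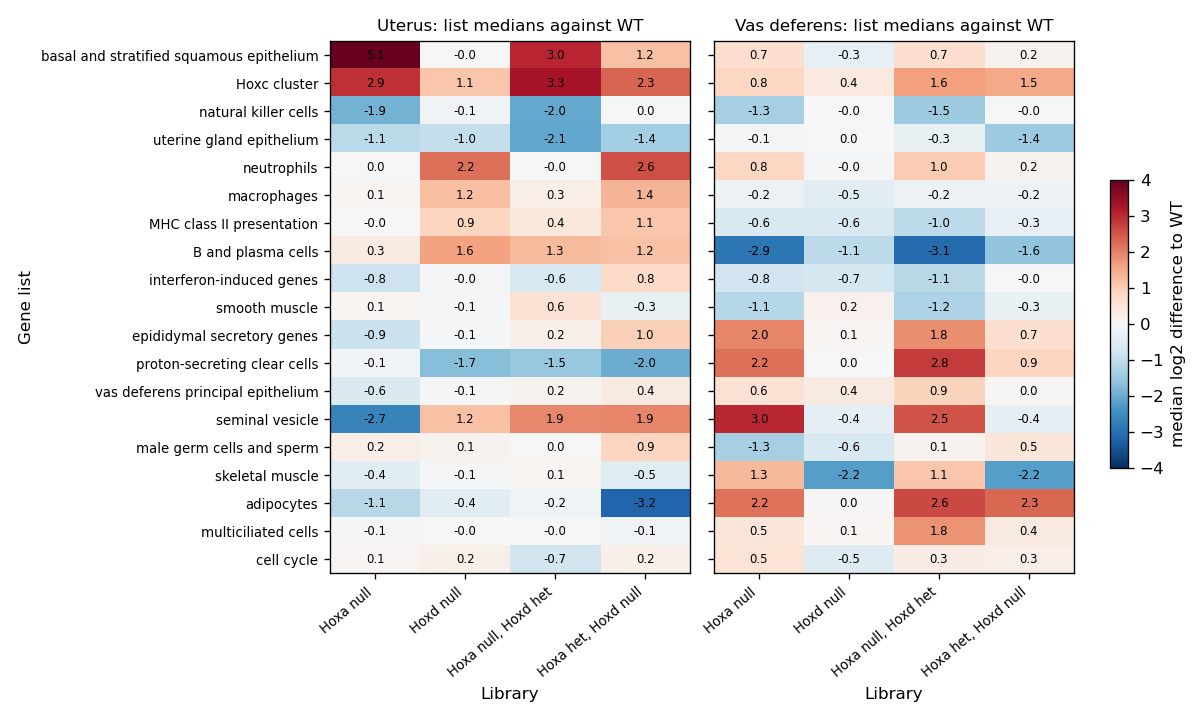
Median log2 difference from WT (cell value and colour) of the members of fixed gene lists (vertical axis) in the 4 mutant uterus and 4 mutant vas deferens libraries (horizontal axis). Basal and stratified squamous genes reach 5.08 in the Hoxa-null uterus, and adipocyte genes reach 2.65 in the compound Hoxa-null vas deferens.

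In the Hoxa-null vasa deferentia epididymal secretory genes were higher than in WT and smooth muscle genes lower, while male germ cell genes went both ways. Both Hoxa-null vasa deferentia lay at least 2-fold above all 3 Hoxa-intact ones for 693 genes and below them for 386. Pde11a, a cyclic nucleotide phosphodiesterase, had the widest separation on the higher side and was at 7.10 and 6.87 in the Hoxa-null and compound Hoxa-null library. Tekt1 and Tekt3, which encode filament proteins of cilia and flagella, were at 4.78 and 7.79, and 4.88 and 7.54. The testis chaperone gene Clgn was at 4.85 and 7.50, Mael, a gene of the piRNA pathway, at 4.80 and 7.74, and the kinesin gene Kif2b at 4.59 and 7.41. Hdgfl1, Qrich2, Morc2b, Lypd4 and Tcte1 had gaps from 4.28 to 4.99, and Myh4, a fast skeletal muscle myosin, was at 4.37 and 4.35. On the lower side were Grid1, a delta glutamate receptor, at -7.05 and -7.55, the potassium channel subunit gene Kcnv2 at -7.72 and -8.60, Wif1, a secreted Wnt inhibitor, at -5.38 and -8.58, the neuropeptide gene Nmu at -5.67 and -6.31 and Ntsr1, a neurotensin receptor, at -3.48 and -3.53. Also lower were Tex11, a meiosis gene, at -5.20 and -4.37, Prm2, a protamine of sperm chromatin, at -5.37 and -5.13, the receptor phosphatase gene Ptprz1 at -3.59 and -6.22 and Hoxa13 at -3.56 and -3.61, while Nsg2, Mug1 and Hpse2 had gaps of 4.89, 3.67 and 3.54.

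Smooth muscle genes had 11 of 16 members at least 2-fold lower in each Hoxa-null vas deferens, with medians of -1.13 and -1.24 at percentiles of 0 and 0, and included the smooth muscle actin gene Actg2 at -1.45 and -1.82 and the potassium channel subunit gene Kcnmb1 at -1.84 and -2.27. Epididymal secretory genes had 21 and 18 of 28 higher, with medians of 1.97 and 1.84, both at percentile 100, and with Rnase9 at 5.08 and 5.08 and Spag11a at 4.86 and 4.63. Clear cells, the proton-secreting cells of the epididymis, had 6 of 8 genes higher in both, with their transcription factor Foxi1 at 3.10 and 3.65 and the proton pump gene Atp6v1b1 at 2.95 and 3.51. Seminal vesicle secretory genes were higher, 6 and 5 of 7, with Semg1 at 3.63 and 3.24. Male germ cell genes went both ways: 2 higher and 7 lower of 14 in the Hoxa-null, 6 and 4 in the compound Hoxa-null library, with Ldhc at 4.03 and 6.59 and the acrosomal gene Acrv1 at 3.66 and 5.84 but Prm1 at -4.35 and -5.14. Markers of other cell types moved with these groups: 10 of 11 adipocyte genes were higher in each, with Adipoq at 2.63 and 2.65, 8 and 7 of 12 skeletal muscle genes were higher, and 9 and 8 of 11 B and plasma cell genes were lower, with Cd79a at -3.34 and -3.94. Genes of Wnt signalling also went both ways, 9 higher and 9 lower of 47 in the Hoxa-null and 11 and 12 in the compound Hoxa-null library, with medians of -0.13 and -0.22. Axin2, a feedback target of the pathway, was at 2.52 and 2.49 and the receptor gene Lgr5 at -3.32 and -3.05. The other 8 pairs gave at most 83 higher genes, for the 2 compound mutants, and 342 lower, for WT with Hoxd-null. Lane 2 alone gave 1587 higher and 846 lower genes between the Hoxa-null libraries and the Hoxd-null vas deferens, leaving out the WT library gave 821 and 499, and leaving out the Hoxa-null library gave 1301 and 628, the compound Hoxa-null library 654 lower and the compound Hoxd-null library 1144 higher.

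The genes that separated the 2 Hoxd-null vasa deferentia from the 3 others included genes of skeletal muscle on the lower side and Cartpt, a neuropeptide gene, on the higher side. Both Hoxd-null vasa deferentia lay at least 2-fold above all 3 Hoxd-intact ones for 24 genes and below them for 103. Cartpt was at 9.11 and 6.63 in the Hoxd-null and compound Hoxd-null library, separated by 4.66 log2 units. The inward-rectifier potassium channel genes Kcnj5 and Kcnj1 were at 2.65 and 1.97, and 1.79 and 2.20, Sox11, a transcription factor of developing neurons, at 1.57 and 1.65, Cyp4a32, a fatty acid hydroxylase gene, at 3.28 and 2.49, the epididymal cystatin gene Cst8 at 2.92 and 3.86 and the basement membrane gene Frem2 at 1.30 and 1.23. Lzts1, Snx31, Ahnak2, B3gat1 and Klf8 had gaps from 1.19 to 2.06. The 12 most separated lower genes were all genes of striated muscle or abundant there: Xirp2 at -7.10 and -6.72, the myosin heavy chain genes Myh1, Myh2 and Myh4 at -6.85 and -5.37, -6.69 and -5.32, and -4.69 and -4.94, the fast-muscle calcium pump gene Atp2a1 at -5.40 and -5.10, the calcium buffer gene Pvalb at -4.98 and -4.99, and Ampd1, Eef1a2, Lmod2, Myh13, Ckmt2 and Mylpf with gaps from 3.27 to 5.05. Of 12 measured skeletal muscle genes, 6 and 9 were at least 2-fold lower and 0 and 0 higher, with medians of -2.21 and -2.22 at percentiles of 0 and 0. Smooth muscle genes had medians of 0.17 and -0.27. This separation was no larger than that of another pair, since WT with Hoxd-null gave 44 higher and 342 lower genes. The 24 higher genes became 49 without the minimum on coverage and 43 with a minimum of 5 normalised reads. Without the WT library the separation held 499 higher and 821 lower genes, the mirror image of the Hoxa comparison, which cannot separate the clusters. It held 218 and 396 without the Hoxd-null library, 91 and 348 without the compound Hoxd-null library and 69 higher without the compound Hoxa-null library.

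Each mutant vas deferens was also compared with WT alone. The Hoxa-null vas deferens had 1839 higher and 1422 lower genes of 16901 measured, led by Chga, a chromogranin of neuroendocrine granules, Spink6 and the whey acidic protein family gene Wfdc12, and on the lower side by Kcnv2, Grid1, Fam151a and the myeloid receptor gene Trem1. In the compound Hoxa-null vas deferens 2370 genes were higher and 1415 lower, led by testis genes: Pabpc2 at 9.16, Actl7b at 8.82, Gykl1 at 8.34, Ddx25, an RNA helicase of spermatids, at 8.30 and Ldhal6b at 7.97. The Hoxd-null vas deferens had 565 higher and 822 lower genes, and 671 and 1615 against the mean of the 3 Hoxd-intact vasa deferentia. After Cartpt its highest were Pld5, Glycam1, an adhesion molecule gene of lymph node venules, at 4.92, the Y-linked Usp9y and Raet1d at 4.12. In the compound Hoxd-null vas deferens 1305 genes were higher and 892 lower, or 946 and 1318 against that mean, and its highest genes were secretory genes of the lung, the surfactant protein genes Sftpc and Sftpa1 at 8.09 and 7.37 and the club cell gene Scgb1a1 at 7.14. This library came from the separate run, and the origin of its lung transcripts was not tested. Adipocyte genes were higher there as well, 10 of 11, against 1 in the Hoxd-null library. Pbsn, a prostate gene, was at -5.83, -9.01, -9.00 and -7.63 in the Hoxa-null, Hoxd-null, compound Hoxa-null and compound Hoxd-null vas deferens, the coagulating gland gene Tgm4 at -6.66, -8.53, -7.46 and -8.76, and the uterine gland gene Prss29 was at -6.92, -6.91, -6.91 and -6.91, its WT library sharing lane 1 with the WT uterus. In the same order Pld5 was at 3.90, 6.31, 5.70 and 6.18, Usp9y at 3.68, 4.80, 2.82 and 5.50 and Chga at 7.20, 2.29, 6.34 and 5.76. Spink6 was at 6.39, 2.73, 6.61 and 4.25, Wfdc12 at 6.04, 0.76, 5.48 and 3.16, Fam151a at -6.89, -2.03, -3.89 and -3.26 and Trem1 at -6.84, -5.87, -5.01 and -4.88. The WT library was the lowest or highest of the 5 for these genes. Against the mean of the intact libraries Chga, Spink6 and Fam151a turned to -2.23, -1.60 and 1.56 in the Hoxd-null vas deferens, Spink6, Wfdc12 and Fam151a to -0.087, -0.68 and 0.33 in the compound Hoxd-null, Usp9y to -0.61 in the compound Hoxa-null and Pld5 to -0.26 in the Hoxa-null vas deferens. The WT vas deferens was the only vas deferens library in lane 1, so differences from it cannot be told apart from the lane. The compound Hoxa-null library differed from the Hoxa-null library by 1271 higher and 321 lower genes, 512 lower without the minimum on coverage, and the compound Hoxd-null from the Hoxd-null library by 1357 and 663, the latter pair across sequencing runs. Of 27 genes of multiciliated cells, many of them shared with flagella, 9 were at least 2-fold above WT and 3 below in the Hoxa-null and 19 above and 2 below in the compound Hoxa-null vas deferens, with Spag6 at 3.96 and 6.97. The compound Hoxa-null library stood apart from all 4 other vas deferens libraries for 784 higher genes, against 45 to 148 for each of the others, so the first of these pairs also holds a library that stands apart.

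The caudal epididymis was compared with the vas deferens as the next more anterior male segment. Its highest named genes were Mep1a, a meprin metalloprotease, at 10.79, the sperm-coating protein gene Crisp4 at 8.93, the bactericidal protein gene Bpi at 8.98, Cyp17a1, a steroid 17-hydroxylase, at 8.45, neuropeptide Y gene Npy at 8.23, the carbonic anhydrase gene Car4 at 8.10, the beta-defensin genes Defb22 and Defb23 at 9.10 and 8.40, and Cdhr2, Cyp2c39, Wfdc13 and Tsnaxip1 between 7.97 and 9.33. All 8 clear cell genes, 20 of 28 epididymal secretory genes and all 14 male germ cell genes were at least 2-fold higher, with medians of 4.31, 3.40 and 4.16. Lower in the epididymis were Nrk at -9.55, Kcnv2 at -8.59, Hes5, a Notch target, at -8.18, the transporter gene Abcg2 at -6.92, and Hpse2, Grid1, Ptprz1, Slc38a3, Tgm4, Prss29 and Pbsn between -9.00 and -6.86. Of 16 smooth muscle genes, 15 were lower, with a median of -1.80. Tgm4, Prss29 and Pbsn were also far below WT in each mutant vas deferens, so for these genes the contrast rests on the WT vas deferens. Prss29 was 6.91 log2 units higher there than in any other male library. In all, 1584 genes were at least 4-fold higher and 664 lower, across different sequencing runs.

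The Hoxa-null vasa deferentia differed from WT in the direction of the epididymis on both sides of this contrast. Over 1550 genes at least 4-fold higher in the epididymis than in the Hoxd-null vasa deferentia, the median difference from WT was 1.18 in the Hoxa-null and 2.23 in the compound Hoxa-null library (both percentile 100), and 838 and 1076 of them were at least 2-fold higher than WT. Over 667 genes lower in the epididymis the medians were -0.90 and -0.83 (both percentile 0). As for the uterus, these percentiles do not measure the spread between libraries. The epididymis library also held male germ cell transcripts, so genes high in it need not come from the duct itself. Male germ cell genes went both ways in the Hoxa-null libraries, as given above. In the compound Hoxd-null vas deferens the medians were 0.37 over 770 genes (percentile 100) and 0.26 over 497 (percentile 99.95), the same sign on both sides. In the Hoxd-null vas deferens the median was -0.11 over the 770 genes, and over the 497 it was the value of genes at the floor in both libraries. With at most 1 library at the floor these were -0.21 over 579 genes (percentile 0) and 0.040 over 462 (percentile 98.7). Of the 693 genes that separated the Hoxa-null vasa deferentia on the higher side, 501 (72.3%) were at least 4-fold higher in the epididymis than the mean of the 3 Hoxa-intact vasa deferentia, and of the 386 lower genes, 189 (49.0%) were lower. The same 3 libraries set both comparisons, which builds in overlap. The 2 compound mutants, treated in the same way, gave 60.2% of 83 higher genes and WT with Hoxd-null 19.6% of 342 lower genes, and all 8 other pairs, some of fewer than 10 genes, ranged from 9.09 to 87.5% and from 0 to 60.0%. With the epididymis set against WT alone, the Hoxa-null shares were 74.5 and 50.8%. The 8 other pairs then gave at most 71.4% (of 7 genes) and 33.3% (of 6), and pairs that hold WT are lowered by construction. Against the WT vas deferens, the epididymis was at 6.05 for Tekt1 and 5.13 for Clgn, and Prm2 was at 3.41 in the epididymis and at -5.37 and -5.13 in the Hoxa-null libraries. Without the Hoxd-null library in the definition of the lists, the medians of the epididymis-low genes were -0.59 and -0.48 in the Hoxa-null and compound Hoxa-null library. Without the compound Hoxa-null library the Hoxd-null medians were -0.0027, the value of genes at the floor, over epididymis-high and -0.07 over epididymis-low genes. In the compound Hoxd-null library the epididymis-low median was 0.16 without the Hoxa-null and 0.06 without the compound Hoxa-null library. With lists made against WT, which the difference shares, the epididymis-low medians were -1.39 in the compound Hoxa-null and -0.25 in the Hoxd-null library and turned to -0.33 in the compound Hoxd-null library. Without the minimum on coverage the epididymis-high medians of the Hoxd-null and compound Hoxd-null library were -0.0027 and 0.17.

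**Figure D3:**
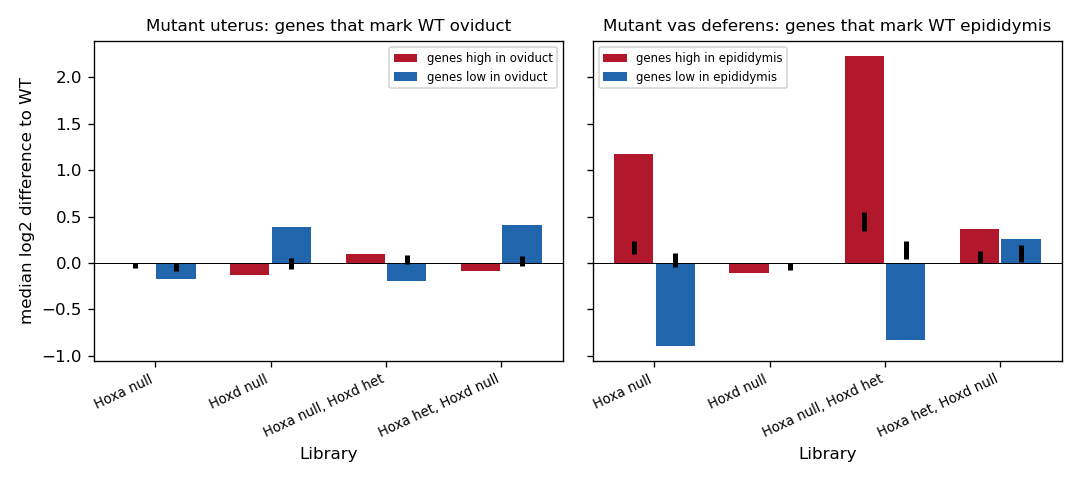
Median log2 difference from WT (bars, vertical axis from 0) of genes high and low in the neighbouring anterior tissue, for each mutant uterus and vas deferens (horizontal axis), with black lines marking the central 95% of medians of 10000 random lists, which shrink to a point where these fall on the value of genes at the floor. The bars of the Hoxa-null and compound Hoxa-null vas deferens reach 1.18 and 2.23 for epididymis-high genes and -0.90 and -0.83 for epididymis-low genes.

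The effects of the same mutation were set side by side in the 2 tissues, which share no library. Across 15553 genes measured in both sexes, the difference between the mean of the Hoxa-null and of the Hoxa-intact libraries had a Spearman correlation of -0.0863 and a Pearson correlation of -0.0214 between uterus and vas deferens, and for Hoxd these were -0.135 and -0.0417. Genes are not independent replicates. A small set separated the Hoxa-null libraries in both tissues: 13 genes were higher in both where independent lists would share 3.00, and 12 were lower in both where they would share 2.59, but 8 and 14 went in opposite directions where 2.71 and 2.87 would be shared. Lower in both were Hoxa11, Wif1, at -1.47 and -3.66 in the uterus, the gastrin-releasing peptide gene Grp at -3.74 and -3.66 in the uterus and -3.45 and -3.69 in the vas deferens, Chi3l1 at -2.39 and -4.67, and -2.49 and -2.98, and Gzma. Higher in both were Slco1a5, at 3.68 and 4.03 in the vas deferens, Fgfbp1 at 2.26 and 1.68 and the receptor tyrosine kinase gene Ret at 1.96 and 1.98, and 1.07 and 2.07. The genes named here outside the fixed rule, Grp, Chi3l1, Ret and S100g, were chosen after their values were seen. For Hoxd, 1 gene was shared, the calcium-binding protein gene S100g, lower at -2.54 and -3.04 in the uterus and -2.27 and -4.82 in the vas deferens. The Hoxd rank correlation was -0.0207 without the Hoxd-null uterus and -0.0711 without the compound Hoxa-null uterus, and the Hoxa rank correlation was -0.0537 without the Hoxa-null and -0.0574 without the Hoxd-null vas deferens.

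**Figure D4:**
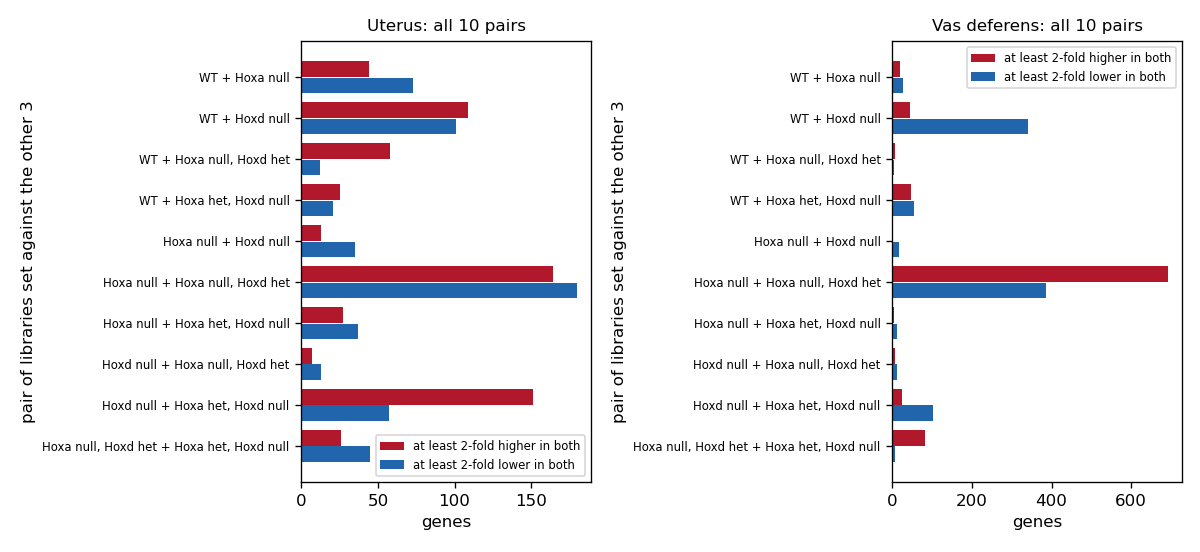
Number of genes for which a pair of libraries lies at least 2-fold above or below the other 3 libraries of the tissue (horizontal axis, counts), for each of the 10 pairs of uterus and of vas deferens libraries (vertical axis). The Hoxa-null pair gives the largest counts in both tissues, 164 and 180 in the uterus and 693 and 386 in the vas deferens.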

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

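Both differences described here were found by comparing the effects of the same mutation in the 2 tissues, and neither difference was tested.

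Mesothelial genes differed from WT in opposite directions in the tissues of Hoxa-null animals. Their median was 1.0 in the Hoxa-null and 1.42 in the compound Hoxa-null uterus but -1.10 and -1.74 in the vas deferens, so that the mean effect was 2.63 log2 units higher in the uterus. Msln, which encodes mesothelin, was at 0.79 and 0.96 in the uterus and -1.87 and -1.87 in the vas deferens, and Upk3b at 1.53 and 2.22 and -0.99 and -1.63. No explanation was tested.

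B and plasma cell genes differed from WT in opposite directions in the tissues of Hoxd-null animals. Their median was 1.62 in the Hoxd-null and 1.17 in the compound Hoxd-null uterus but -1.06 and -1.59 in the vas deferens, a difference of 2.72 log2 units. Ms4a1, which encodes the B cell antigen CD20, was at 1.93 and 1.91 in the uterus and -1.57 and -1.97 in the vas deferens. Against the mean of the 3 Hoxd-intact vasa deferentia the medians in the vas deferens were 0.56 and 0.60. Of these 3 libraries 2 are Hoxa-null, and most B and plasma cell genes were below WT there too. The negative direction thus holds against WT only and is not particular to the Hoxd-null libraries. In the uterus the list median was above WT in both Hoxa-null libraries as well, by at least 2-fold in the compound Hoxa-null uterus. The positive direction is thus not particular to the Hoxd-null uteri either. The medians of the 2 tissues rest on different numbers of measured genes.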

How the results depend on the processing

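The lane subsets and the subset of genes with at most 1 library at the floor were chosen after the data were seen, and the other alternatives before the data were examined. No paired analysis was possible because each group holds 1 library and every replicate number is 1. The planned pseudocount of 0.1 was not run, since the values are log2 values without a pseudocount. The deposited values without removal of the small shifts between libraries gave all 36 counts within 1.5 times and changed no direction of a list, gene or shift. Depth limits the low genes, as relative depth differed by up to 1.51-fold and libraries with at most 1 normalised read stand at the floor. Where a value changed direction, the cause was not tested.

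Without the minimum on coverage, 34 of 36 counts stayed within 1.5 times. The higher genes of the Hoxd-null vas deferens separation numbered 49, and the genes lower in the compound Hoxa-null than in the Hoxa-null vas deferens 512. The epididymis-high medians were 0.88 and 1.91 in the Hoxa-null and compound Hoxa-null vas deferens. With a minimum of 5 normalised reads these were 43 genes and medians of 0.92 and 1.99. The neutrophil median of the compound Hoxa-null vas deferens was -0.0018 under both settings. This is the value of genes at the floor in both libraries, so it shows no direction. With at most 1 library at the floor, the epididymis-high median of the compound Hoxa-null vas deferens was 1.74, and the uterine gland median of the compound Hoxd-null vas deferens turned to 0.62.

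Within lane 1 the Hoxa comparison of the uterus gave 997 higher and 1201 lower genes, within lane 2 870 and 731, and the Hoxd comparison within lane 2 731 and 870. Within lane 2 the Hoxa comparison of the vas deferens gave 1587 and 846. These hold fewer libraries to separate, which raises the counts by construction. Leaving out 1 library had the same effect. The uterus Hoxa separation then ranged from 218 to 568 higher and from 239 to 456 lower genes, and the uterus Hoxd separation from 190 to 425 and from 118 to 297. The vas deferens Hoxa separation ranged from 815 to 1301 and from 499 to 654, and the vas deferens Hoxd separation from 35 to 499 and from 125 to 821.

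With 1 library left out of the tissue definition, the oviduct-high medians ranged from -0.019 to -0.0026 in the Hoxa-null, 0.0011 to 0.14 in the compound Hoxa-null, -0.13 to -0.13 in the Hoxd-null and -0.11 to -0.07 in the compound Hoxd-null uterus. The oviduct-low medians ranged from -0.18 to -0.15, -0.21 to -0.18, 0.22 to 0.54 and 0.27 to 0.50 in the same order. The epididymis-high medians ranged from 1.11 to 1.17 in the Hoxa-null, 2.15 to 2.17 in the compound Hoxa-null, -0.12 to -0.0027 in the Hoxd-null and 0.368 to 0.37 in the compound Hoxd-null vas deferens, and the epididymis-low medians from -0.95 to -0.59, -0.93 to -0.48, -0.07 to -0.0027 and 0.06 to 0.16. The lowest size in the Hoxa-null and compound Hoxa-null vas deferens, -0.59 and -0.48, came without the Hoxd-null library. The rank correlation between tissues ranged from -0.128 to -0.0537 for Hoxa and from -0.199 to -0.0207 for Hoxd.

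With an 8-fold definition of tissue genes, the oviduct-low medians were -0.61, -0.76 and 1.04 in the Hoxa-null, compound Hoxa-null and compound Hoxd-null uterus. The epididymis-high and epididymis-low medians were 1.46 and -1.15 in the Hoxa-null and 3.01 and -1.15 in the compound Hoxa-null vas deferens. With tissue genes defined against WT, which the difference shares, the oviduct-low medians were -0.996 and -1.28 in the Hoxa-null and compound Hoxa-null uterus and turned to -0.14 and -0.17 in the Hoxd-null and compound Hoxd-null uterus, while the oviduct-high median of the compound Hoxa-null uterus was 0.35. In the vas deferens they were 1.46 and -1.34 in the Hoxa-null and 2.46 and -1.39 in the compound Hoxa-null library, and the epididymis-low medians were -0.25 in the Hoxd-null and -0.33, a turned direction, in the compound Hoxd-null library.

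Against the mean of all libraries intact for the mutated cluster, 15 of 16 counts stayed within 1.5 times, and the genes lower in the Hoxd-null vas deferens numbered 1615, beside 671 higher, while the compound Hoxd-null vas deferens had 946 higher and 1318 lower. All 4 counts of the tissue contrasts stayed within 1.5 times against the mean of all 5 libraries of the tissue. Of 670 values of named genes and Hox genes 497 moved by at least 0.2 log2 units without a turned call and 30 turned, and of 368 list medians 208 moved and 6 turned, so most sizes against WT depend on this reference. In the Hoxa-null uterus the gland median was 0.15, Prss28 was at 0.46, Prss29 at 0.34, Ccr3 at -1.45, Retnlg at -2.64 and Kap at -1.65, and in the compound Hoxa-null uterus Kap was at -1.19 and Tm4sf4 at 0.29. In the Hoxd-null uterus the Hoxc median was -1.14, Hoxc4 was at -0.73, Hoxc9 at -1.36, Hoxc10 at -0.76, Hoxc11 at -0.48, Col22a1 at 2.28 and Ttr at 1.45. In the compound Hoxd-null uterus the squamous median was -1.22, the urothelium median -0.12, Hoxa4 was at -0.43, Hoxa5 at -0.061, Hoxa6 at -0.16, Hoxa11 at 0.92, Hoxc4 at -0.0070 and Hoxc8 at -0.58. The intact uteri of the Hoxd comparisons include 2 Hoxa-null libraries, and so do the intact vasa deferentia. In the vas deferens the B and plasma cell medians of the Hoxd-null and compound Hoxd-null library were 0.56 and 0.60, Ms4a1 was at 1.22 and 0.82, and in the Hoxd-null library Hoxc9 was at -0.20, Chga at -2.23, Fam151a at 1.56 and Spink6 at -1.60. Fam151a, Spink6 and Wfdc12 were at 0.33, -0.087 and -0.68 in the compound Hoxd-null library, Usp9y at -0.61 in the compound Hoxa-null library and Pld5 at -0.26 in the Hoxa-null library.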

Other observations

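Of the 8 tests described here, those of uterus-specific genes in the male libraries and of meiosis genes were chosen before their results were seen and the other 6 after.

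Of 23 measured genes of the extracellular matrix and its turnover, 6 and 8 were at least 2-fold higher and 4 and 4 lower in the Hoxa-null and compound Hoxa-null uterus. Mmp7, the matrix metalloprotease matrilysin, was at -2.44 and -2.56, Mmp10 at -2.03 and -1.78 and Tnc, which encodes tenascin C, at -2.05 and -1.59. In the Hoxd-null uterus 9 were higher and 0 lower, with the proteoglycan gene Lum at 1.69, the collagen gene Col1a1 at 1.30 and Mmp3 at 1.89, and in the compound Hoxd-null uterus 4 were higher and 0 lower. Genes of Wnt signalling had 4 higher and 9 lower of 46 in the Hoxa-null uterus, with the ligand gene Wnt10a at 3.24 and the nuclear effector gene Lef1 at -2.65. Of 20 interferon-induced genes, 5 were higher in the compound Hoxd-null uterus, with Mx1 at 1.45 and the interferon regulatory factor gene Irf7 at 1.34.

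In the Hoxa-null vas deferens 3 of 33 genes of Notch, BMP, Hedgehog and FGF signalling were at least 2-fold higher and 7 lower. Ihh, the Indian hedgehog ligand gene, was at 3.70 and the Notch target gene Hey1 at -3.05. Nerve and Schwann cell genes had 2 higher and 7 lower of 9, with Dbh, the dopamine beta-hydroxylase of noradrenergic neurons, at 4.89 and Sox10, a Schwann cell transcription factor, at -2.47. Eosinophil and mast cell genes had 0 higher and 3 lower of 10, with the mast cell protease genes Cpa3 and Cma1 at -1.22 and -1.17.

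Transcripts of the other sex were present in libraries that share a lane with it, but also in the oviduct, which shares no lane with a male library used here and had Kdm5d and Uty at 4.90 and 3.67 and Xist at -1.03 against the WT uterus, a case that lane sharing among these libraries does not cover. Prss28, Prss29, Spink3 and Ttr were 3.47, 6.91, 4.58 and 2.66 log2 units higher in the WT vas deferens, in lane 1 with the WT uterus, than in any other male library, and Xist was higher in all 4 vas deferens libraries that share a lane with uteri than in the separate run. Female tissue in the WT vas deferens sample stays open: Xist there was 1.40 above the compound Hoxd-null vas deferens and at -0.679 relative to the mean of the 3 vas deferens libraries of lane 2, which share that lane with uteri themselves. Reads assigned to the wrong library of a lane may account for male genes in the uteri: for Crisp1, Svs5, Semg1 and Pate4 the difference between lanes was the same in uterus and vas deferens to a median of 0.297 log2 units, with a bound set when the values were known. The test of other genes specific to the WT uterus stays open. It began with 9 genes at least 16-fold higher in the WT uterus than in every other female library. Any of Prss28, Prss29, Spink3 and Ttr among these were left out as already seen, as were genes that did not vary in the male set. Only 3 genes remained, too few to decide, and 0 percent of them were highest in the WT vas deferens. No biological explanation was tested.

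Testis genes such as Clgn, Mael and Ldhc were higher in the Hoxa-null vasa deferentia, while of 6 late spermatid genes 6 were at least 2-fold lower in the Hoxa-null and 4 in the compound Hoxa-null library than the mean of the 3 others. Sperm like those of the WT epididymis are argued against, because the late spermatid genes had medians of -4.0 and -1.88 in these libraries, against 4.0 in the WT epididymis. A candidate explanation is germ cells of earlier stages: 10 measured meiosis genes of 16 listed had medians of 1.92 and 2.28, with 6 and 8 at least 2-fold higher and 1 lower, Tex11, in both libraries. Epididymal tissue stays open, since epididymal secretory genes had medians of 1.71 and 1.71 and the meiosis genes one of 2.07 in the WT epididymis, which they exceeded by a median of 1.24 in the compound Hoxa-null library but not in the Hoxa-null library, at -0.50. A difference in what was dissected and an effect of the Hoxa genotype on the duct stay open, and neither was tested.

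Squamous genes of the Hoxa-null uteri could come from a shift towards the oviduct or from cervical or vaginal tissue in the samples. Both stay open, the first only as a part of the rise. In the WT oviduct 7 of the 14 squamous genes were at least 2-fold higher and 5 lower than in the WT uterus, with a median of 0.465, so their direction there does not decide. The list medians of both Hoxa-null uteri, given above, were higher than this. For the list as a set, this argues against a shift to the level of the oviduct library as the whole source of the rise. Hoxa13 was at 17.1 normalised reads in the Hoxa-null and 8.01 in the compound Hoxa-null uterus, against 2.19 in WT, 1 in the Hoxd-null and 2.74 in the compound Hoxd-null uterus, levels too low to settle whether posterior tissue was present. The squamous median of the compound Hoxd-null uterus also lay at least 2-fold above WT, though it was -1.22 against the mean of the Hoxd-intact uteri. An effect of the Hoxa genotype on the uterine epithelium was not tested.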
